A study of Mus musculus with 6 samples.

How the data were processed

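RNA-seq libraries were made from polyA RNA of MLE-12 mouse lung epithelial cells, 3 given PBS and 3 given cigarette smoke extract (CSE). The groups and replicate numbers were taken from the sample titles. The labels' extraction text speaks of lung tissue whereas each sample is described as the cell line, so markers of other lung cells were among the gene lists. No label says whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

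Each deposited file lists 118489 transcripts with an estimated count and a TPM value for each, per the file headers, whose column names are those of kallisto. TPM is the estimated count divided by effective transcript length and scaled by the authors to the same sum in each library, which removes depth. The submitters' processing notes name kallisto 0.46.2, fastp 0.20.1, FastQC 0.12.1 and DESeq2 1.40.2 and the GRCm38 build, without the role of each tool. The transcript index, trimming settings and strand setting are not given in the sources used here. kallisto shares reads that fit several transcripts among them by a model, so counts of near-identical genes are estimates that one copy can lend to another.

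Transcripts were matched by identifier and version to the GENCODE vM21 annotation of GRCm38, which held 116816 of them (98.6%). The other 1673 transcripts, with 0.638% to 0.664% of a library's counts, were left out. Estimated counts and TPM were summed over the transcripts of each of 36047 genes, and the summed counts were rounded to whole numbers. Library totals lay between 12093009 and 24050167 estimated counts, where 3 counts correspond to between 0.125 and 0.248 CPM. Intervals on counts (95%, conditional exact binomial) cover counting error only, since reads without molecular identifiers are not independent molecules. No libraries of a group were duplicates: chi-square per degree of freedom over genes with at least 20 counts lay between 5.61 and 17.6 within groups.

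Genes were filtered with filterByExpr (minimum count 10) and normalised by TMM, with factors between 0.976 and 1.03. CSE was compared with PBS by edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05, with treatment as the only factor. The biological coefficient of variation was 9.2%. Gene lists were compared with limma's camera on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the 30 lists with at least 3 tested members out of 31 written from textbook knowledge. The test, the lists, the rule for named genes and the alternative settings, except for the GC correction, were fixed before the data were examined. Named genes were the 10 largest increases and the 10 largest decreases among changed genes with at least 5 TPM in a group, groups that do not overlap and a symbol that is not a gene model or pseudogene, together with 8 genes chosen from the series title (Cd36, Zbp1, Mlkl, Ripk3, Pnpla2, Lipe, Mgll and Plin2), and in each list the 3 members of smallest p, or 4 where the list was called. Not every gene the rule named is described. Other genes named with values, such as Hmox1, Ahrr, Cyp1b1, Ddit3, Cdh5 and Ptprc, and genes named for losing their call with 1 library left out, were chosen after their values were seen. Genes were searched for shared sequence by counting the 31-base words of their most abundant transcript that occur in transcripts of other genes. Positions are those of the annotation, on GRCm38.

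Gene symbols of the lists were matched to the annotation directly or through RefSeq synonyms, and 1 symbol, Rigi, had no match. Alternatives were RLE and library-size scaling, DESeq2, limma-voom, no filter on low counts, a minimum mean of 5 CPM, an offset for mean effective transcript length, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean of at least 1 TPM, a test against a 1.5-fold change, the replicate number as a block, each library left out in turn, and for lists camera with an estimated correlation and fry. Removal of each library's GC and length trend, by loess with a span of 0.5, was chosen after seeing the data. The procedure was tested on simulated counts for 13451 genes with the means and depths of this comparison. Of these, 200 were changed by 1.5-fold or 2-fold, and the genes of 2 of 30 simulated lists were shifted besides. The procedure recovered 60% of genes changed 1.5-fold and 78% of genes changed 2-fold, 6.7% of its calls fell on unchanged genes, and with no change simulated it called 2 genes. Fewer genes were changed than the 1539 called in the data. The adjustment depends on that share, so these rates describe the simulation's setting only. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.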

Results

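Gene expression was measured by RNA-seq in MLE-12 cells, a mouse lung epithelial line immortalised with a viral large T antigen. Cells received either PBS (3 libraries) or cigarette smoke extract (CSE, 3 libraries), a solution of smoke constituents that is added to the culture medium. CSE was used at 5% and an optical density of 2, was added when the cultures had reached 30% density, and the cells were collected after 24 h. The PBS libraries held 13647897, 18082404 and 19486697 estimated counts, and the CSE libraries 12093009, 24050167 and 17075604. Mitochondrially encoded genes took 2.32%, 2.65% and 2.19% of the counts in the PBS libraries and 2.47%, 2.54% and 2.89% in the CSE libraries. The 10 most abundant genes took 4.13%, 4.15% and 3.78% of the counts in the PBS libraries and 4.46%, 4.52% and 4.79% in the CSE libraries, so the groups did not overlap in this share. Correlations of log2 CPM (counts scaled to library size) across genes lay between 0.987 and 0.993 for libraries of one group and between 0.981 and 0.987 for libraries of different groups, and the first principal component, with 42.8% of the variance, separated the groups.

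The comparison of CSE with PBS asked which genes and pathways of the epithelial cells respond to smoke extract. Genes of xenobiotic metabolism were among those with the largest increases. Cyp1a1, a cytochrome P450 and the classical target of the aryl hydrocarbon receptor (AhR), rose from a mean of 0.0623 ± 0.0137 TPM to 34.5 ± 3.26 TPM (SD, n = 3). The aldehyde dehydrogenase Aldh3a1 rose by 2.84 ± 0.10 on the log2 scale (SE), from 37.6 to 255 TPM, and the ADP-ribosyltransferase Tiparp by 2.40 ± 0.07. The glutathione S-transferase Gsta3 rose by 2.39 ± 0.13 and the carboxylesterase Ces1g by 2.44 ± 0.19. In the other direction, Tek, which encodes an angiopoietin receptor, fell by 2.76 ± 0.13, the water channel Aqp1 fell by 2.05 ± 0.12 and mesothelin, Msln, fell by 1.69 ± 0.11, from 109 ± 17.7 to 32.1 ± 2.19 TPM.

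Of 13451 genes tested, 1539 changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 581 higher and 958 lower in CSE. Of these, 88 were at least 2-fold higher and 136 at least 2-fold lower. The 3 libraries of one group lay apart from the 3 of the other in 4202 tested genes (31.2%), against 10% by chance. The balance of directions varied between settings, little with other scaling factors (582 higher and 963 lower with RLE, 548 and 987 with library size) and more elsewhere: the counts were 224 higher and 774 lower with limma on log2(TPM + 1), 1052 higher and 1145 lower with no filter on low counts, 967 higher and 974 lower without PBS replicate 1, and 920 higher and 863 lower after a GC and length trend was removed from each library. The number of changed genes moved by over 1.5 times when any of 3 libraries was left out, to 963 without PBS replicate 3, 859 without CSE replicate 2 and 837 without CSE replicate 3.

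The 10 genes with the largest increases among those expressed at 5 TPM or more also held Gsta1, Slc22a14, Irx3, Afp and Ugt1a6a. The organic ion transporter family member Slc22a14 rose by 2.76 ± 0.23, the homeobox gene Irx3 by 2.46 ± 0.20 and alpha-fetoprotein, Afp, by 2.39 ± 0.29, each from under 2 TPM in PBS. Gsta1 rose by 3.76 ± 0.14 and Ugt1a6a by 2.11 ± 0.09, but 92.2% of the 31-base words of Gsta1 and all of those of Ugt1a6a (100%) also occur in transcripts of other genes, so their counts are uncertain. The 10 largest decreases were those of Tek, Aqp1 and Msln together with Myl7 (fell by 2.08 ± 0.23), Srpk3 (fell by 2.06 ± 0.35), Ckmt1 (fell by 2.02 ± 0.20), Nppb (fell by 1.96 ± 0.25), Fam19a4 (fell by 1.83 ± 0.18), Serpinb6c (fell by 1.78 ± 0.20) and Fam180a (fell by 1.67 ± 0.09). Srpk3 varied widely between PBS libraries (8.79 ± 5.47 TPM, SD, n = 3).

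**Figure D1:**
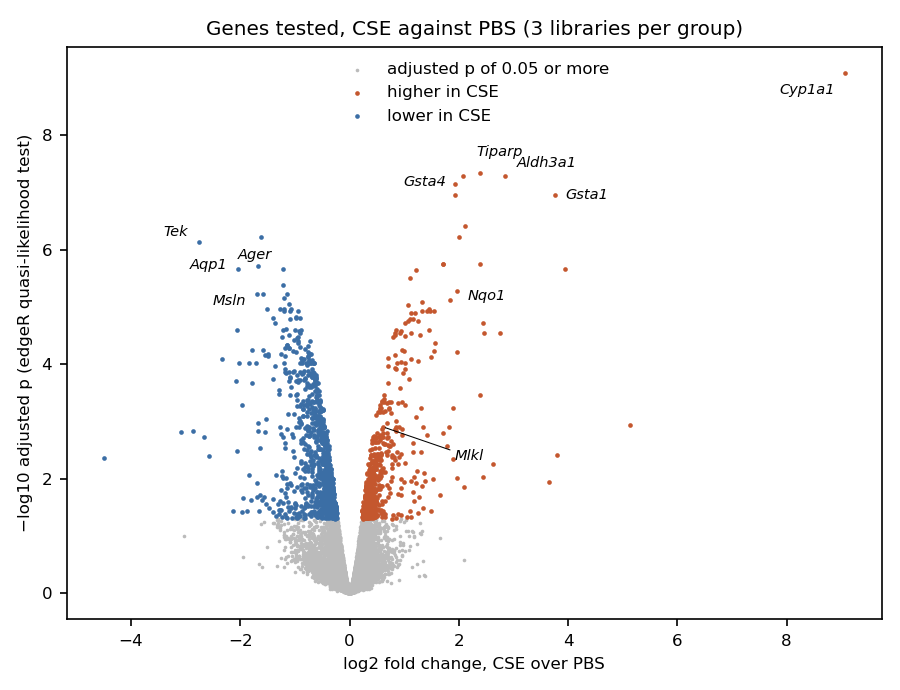
Log2 fold change of each of the 13451 tested genes (x axis, CSE over PBS, 3 libraries per group) against −log10 of its adjusted p in edgeR's quasi-likelihood test (y axis). Orange points are the 581 genes higher in CSE, blue points the 958 lower, grey points the genes at an adjusted p of 0.05 or more, and Cyp1a1 lies far to the right at 9.07.

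Targets of AhR rose as a group. Of 8 tested members, 7 rose, and the same number rose when p-values were adjusted over the list alone. Their median log2 change was 2.04 (limma camera, adjusted p = 3.66e-13, and adjusted p = 0.049 with an estimated correlation). Cyp1a1 (chromosome 9, 57687928 to 57703824, GRCm38) changed by 9.07 ± 0.18 on the log2 scale in edgeR's fit (adjusted p = 8.08e-10). Its PBS libraries held 5 counts in total against 2913 in the CSE libraries, a depth-scaled ratio of 561 with a 95% counting interval of 240 to 1730. Nqo1, a quinone reductase shared with the NRF2 list, rose by 1.97 ± 0.12, from 54.3 to 200 TPM, and Cyp1b1 by 1.48 ± 0.10. The AhR repressor gene Ahrr was not called, at 0.33 ± 0.29 and under 1 TPM in both groups.

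Targets of NRF2, the regulator of antioxidant and glutathione genes, were also higher. Of 24 tested, 16 rose and 8 were not called, and 20 rose when adjusted over the list alone. With 1 library left out, the count of risen genes lay between 11 and 19. It was 11 without PBS replicate 2, PBS replicate 3, CSE replicate 2 or CSE replicate 3, and 19 without PBS replicate 1. Gsta4 rose by 1.92 ± 0.07, from 80.4 to 285 TPM. The cystine transporter Slc7a11 rose by 1.72 ± 0.09 and Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, by 1.33 ± 0.09, from 523 to 1270 TPM. Heme oxygenase, Hmox1, often used as a marker of this pathway, was not called, with 103 TPM in PBS and 111 TPM in CSE (0.20 ± 0.07, edgeR adjusted p = 0.0885). The list's median was 0.42 (camera, adjusted p = 5.63e-13), and this call did not hold at an adjusted p = 0.296 with an estimated correlation.

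Genes of the ATF4 program, which supplies amino acids under stress, rose in part. Of 23 tested, 10 rose, Atf3 fell and 12 were not called, while 13 rose when adjusted over the list alone. The largest rise was that of Slc7a11, which is shared with the NRF2 list. With PBS replicate 3 or CSE replicate 2 left out, 5 of the 10 kept their call, and Trib3, Mthfd2, Psat1, Sesn2 and Chac1 did not. Asparagine synthetase, Asns, rose by 0.61 ± 0.08, from 278 to 405 TPM, the amino acid carrier subunit Slc3a2 by 0.49 ± 0.08 and Shmt2, a mitochondrial enzyme of serine metabolism, by 0.49 ± 0.09. Atf3 fell by 0.57 ± 0.16, and the stress gene Ddit3 had 20.6 TPM in PBS and 20.9 TPM in CSE. The median was 0.24 (camera, adjusted p = 8.14e-06, and adjusted p = 0.371 with an estimated correlation). None of 19 endoplasmic reticulum chaperone genes was called by edgeR (unadjusted p under 0.05 for 1, DESeq2 called 1 and limma-voom 0), and the list was not called (camera, adjusted p = 0.723). In the heat shock list, 3 of 17 genes rose, Hspd1 by 0.45 ± 0.07, Hspe1 by 0.71 ± 0.17 and Hspa4l by 0.32 ± 0.09, and the list was not called (camera, adjusted p = 0.101). Without PBS replicate 3, CSE replicate 2 or CSE replicate 3, 1 heat shock gene was called, and without PBS replicate 2, 1 chaperone gene was lower.

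Cholesterol synthesis genes were lower throughout the pathway. All 23 tested members had lower fitted values, 21 of them fell at the threshold, and all 23 fell when adjusted over the list alone. Insig1, which encodes a sterol-regulated inhibitor of SREBP processing, fell by 1.02 ± 0.09, from 122 to 57.6 TPM. The isomerase Idi1 fell by 0.95 ± 0.08, from 245 to 119 TPM, and Nsdhl by 0.75 ± 0.07. The median log2 change was −0.57 (camera, adjusted p = 5.21e-18, and adjusted p = 0.049 with an estimated correlation). Among fatty acid and triglyceride synthesis genes, the elongase Elovl6 fell by 1.14 ± 0.10 and fatty acid synthase, Fasn, fell by 0.52 ± 0.08, from 436 to 271 TPM, and the other 17 of 19 were not called. Adjusted over the list alone, 5 fell, and without PBS replicate 2, 7 were called lower over all genes. This list's median was −0.21 (camera, adjusted p = 0.000921, and adjusted p = 0.188 with an estimated correlation).

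Markers of alveolar type 1 cells, the flat cells of the gas exchange surface, were lower in CSE. Of 13 tested, 8 fell, both over all genes and adjusted over the list alone, and every tested member had a lower fitted value. The receptor gene Ager fell by 1.23 ± 0.07, from 183 to 73.5 TPM, Hopx by 0.68 ± 0.09, the receptor Gprc5a by 0.64 ± 0.07 and Emp2 by 0.55 ± 0.08. The median was −0.55 (camera, adjusted p = 3.96e-08, and adjusted p = 0.102 with an estimated correlation). Genes of epithelial structure fell as well, 8 of 13 by each adjustment, but only 5 without PBS replicate 3 or without CSE replicate 2, when Ocln, Esrp1 and Krt8 were not called. Keratin 19, Krt19, fell by 0.88 ± 0.09, from 1010 to 493 TPM, the desmosome genes Jup and Dsp fell by 0.70 ± 0.07 and 0.75 ± 0.09, and the tight junction gene Cldn3 fell by 0.85 ± 0.12. Their median was −0.69 (camera, adjusted p = 1.69e-05, and adjusted p = 0.102 with an estimated correlation). Of 11 tested alveolar type 2 markers, Lpcat1 fell by 0.35 ± 0.08 and surfactant protein C, Sftpc, fell by 1.57 ± 0.37 from 3.09 TPM, and the list was not called (camera, adjusted p = 0.196). The Sftpc call was lost with DESeq2 and without any of 4 libraries, up to an edgeR adjusted p = 0.113 without CSE replicate 2, and neither gene was called without CSE replicate 1 or CSE replicate 2.

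**Figure D2:**
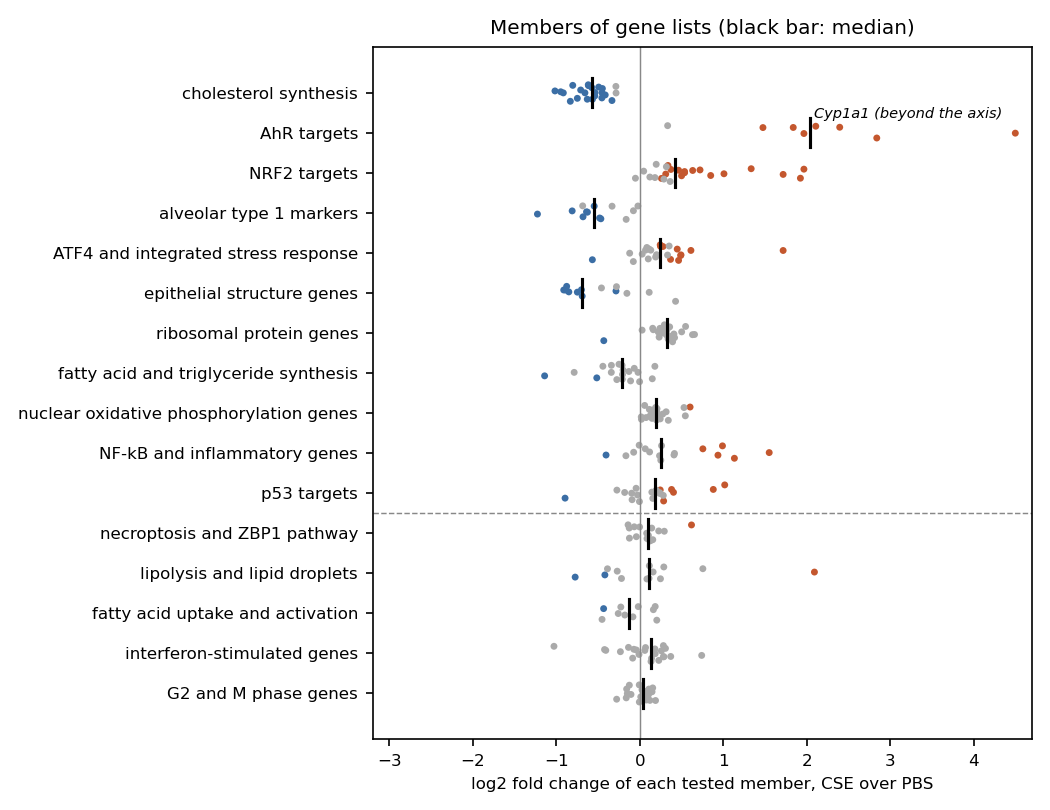
Log2 fold change, CSE over PBS, of each tested member (points) of 16 gene lists, with the median as a black bar. Orange and blue points are genes called higher and lower by edgeR, grey points were not called, and Cyp1a1 at 9.07 is drawn at the right edge. The 11 lists above the dashed line were called by camera, with medians from −0.69 for epithelial structure genes to 2.04 for AhR targets, and the 5 below it were not.

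Inflammatory genes split. Of 16 tested members of the NF-kB list, 5 rose, Vcam1 fell and 10 were not called. Ptgs2, which encodes an inducible cyclooxygenase, rose by 1.55 ± 0.11, from 6.67 to 19.0 TPM. Nfkbiz rose by 1.13 ± 0.08, the chemokine gene Ccl2 by 0.76 ± 0.12, Lcn2 by 0.94 ± 0.20 and the acute phase gene Saa3 by 0.99 ± 0.21, while Vcam1 fell by 0.40 ± 0.07. Adjusted over the list alone, 6 rose and 1 fell. The median was 0.26 (camera, adjusted p = 0.00991, and adjusted p = 0.188 with an estimated correlation). Of 21 p53 targets, 6 rose, including Plk2 (1.02 ± 0.09), the death receptor gene Fas (0.88 ± 0.11, from 32.7 to 55.6 TPM) and the cell cycle inhibitor Cdkn1a (0.40 ± 0.07), while Perp, which encodes a desmosome-associated protein, fell by 0.90 ± 0.15. Adjusted over the list alone, 7 rose and 1 fell. Without CSE replicate 3, 3 of the 6 kept their call, and Sesn1 (edgeR adjusted p = 0.0625), Ccng1 (0.141) and Sesn2 did not. The p53 median was 0.19 (camera, adjusted p = 0.0259, and adjusted p = 0.371 with an estimated correlation), and its call was lost without PBS replicate 1 (adjusted p = 0.0707), PBS replicate 2 (0.08) or CSE replicate 2 (0.0595).

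Ribosomal protein genes and nuclear genes of oxidative phosphorylation were called higher by camera although almost none of their members was called singly with all 6 libraries. Without PBS replicate 1, 18 ribosomal protein genes and 10 oxidative phosphorylation genes were called higher by edgeR. Of 25 ribosomal protein genes, 24 had higher fitted values, 16 of these at an unadjusted p under 0.05. The edgeR test called 0 of them higher (DESeq2 called 5 higher, limma-voom 0) and Rpl5, 94.8% of whose 31-base words occur in other transcripts, fell by 0.43 ± 0.10. Members with higher fitted values share words too, 78.0% for Rpl18, 63.1% for Rpl11 and 56.2% for Rps20, so counts are uncertain in both directions. The list's median was 0.32 (camera, adjusted p = 0.000357, and adjusted p = 0.542 with an estimated correlation). All 27 oxidative phosphorylation genes had higher fitted values, Ndufb3 rose by 0.60 ± 0.17, and none passed when adjusted over the list alone. Their median was 0.19 (camera, adjusted p = 0.00108, and adjusted p = 0.542 with an estimated correlation), and the call was lost after the GC and length trend was removed (adjusted p = 0.0612). Libraries of one group differed in these genes: relative to the PBS mean, the ribosomal protein genes averaged 0.28, −0.16 and −0.12 in the PBS libraries and 0.10, 0.30 and 0.55 in the CSE libraries. None of 13 mitochondrially encoded genes was called by edgeR, DESeq2 or limma-voom, 0 of them had an unadjusted p under 0.05, and the list was not called (camera, adjusted p = 0.196).

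The series title names lipolysis, CD36 and ZBP1-mediated necrosis, and the genes of these processes were examined individually. Mlkl, which encodes the membrane-permeabilising effector of necroptosis (chromosome 8, 111311797 to 111338177), rose by 0.62 ± 0.09, from 32.0 ± 2.73 to 46.7 ± 2.50 TPM (SD, n = 3; edgeR adjusted p = 0.00125), and was higher in each CSE library than in each PBS library. Ripk3, which encodes the kinase that activates MLKL, was not called at 0.16 ± 0.32 (edgeR adjusted p = 0.805) on 44 counts in PBS and 50 in CSE, and its sign turned with an offset for effective length (−0.08) and on the TPM scale. Zbp1 had 13 counts over the PBS libraries and 17 over the CSE libraries, too few for the model. Its depth-scaled ratio was 1.26 with a 95% counting interval of 0.576 to 2.82, so a difference was not detectable at this depth (two-sided exact permutation p = 0.5, where 3 against 3 libraries allow no p under 0.1). Cd36, which encodes a fatty acid uptake receptor, had 8 and 14 counts, a ratio of 1.68 with an interval of 0.659 to 4.63 (exact permutation p = 0.3). Of 16 tested genes of the necroptosis list, Mlkl alone was called, by each adjustment (2 genes were called without PBS replicate 2), and the list was not called (camera, adjusted p = 0.201).

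Lipolysis genes moved in both directions. Monoglyceride lipase, Mgll, fell by 0.77 ± 0.10, from 15.5 to 9.53 TPM (edgeR adjusted p = 0.00054). Hormone-sensitive lipase, Lipe, fell by 0.42 ± 0.11 (edgeR adjusted p = 0.0385), a call that was lost with DESeq2 (adjusted p = 0.0528), with limma on log2(TPM + 1) (0.0914), with an offset for effective length (0.0539), after removal of the GC and length trend (0.0797) and without each library in turn except PBS replicate 1 (0.0798 to 0.161). Adipose triglyceride lipase, Pnpla2, stood at the threshold, at −0.27 ± 0.08 (edgeR adjusted p = 0.0509), with 107 TPM in PBS and 83.8 TPM in CSE, and passed it with DESeq2 (adjusted p = 0.0371) and with limma on log2(TPM + 1) (0.0301). The lipid droplet coat gene Plin2 was not called (0.25 ± 0.08, edgeR adjusted p = 0.088). Ces1d rose by 2.09 ± 0.46 on 11 counts in PBS and 49 in CSE, and its call was lost with DESeq2. Over the 13 tested genes of the list, 1 rose and 2 fell, or 2 rose and 4 fell when adjusted over the list alone, and the list was not called (camera, adjusted p = 0.975). In the fatty acid uptake list, Slc27a1 alone of 10 fell, by −0.43 ± 0.10 (2 fell without PBS replicate 2 and 1 rose without PBS replicate 1), and the list was not called (camera, adjusted p = 0.379).

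**Figure D3:**
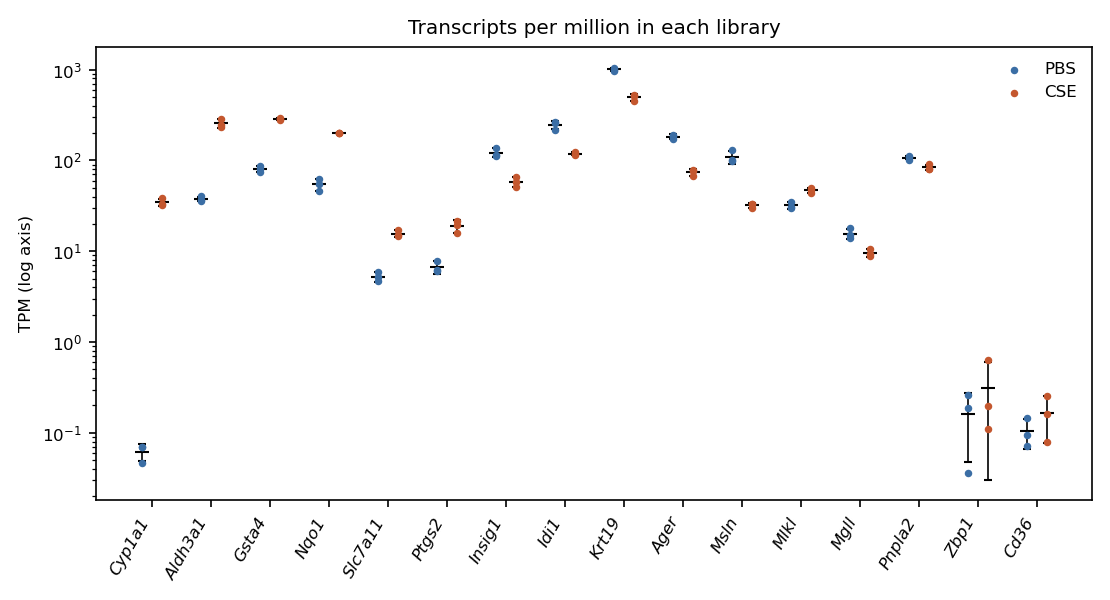
TPM of 16 genes in each library (points, log axis), with the mean and SD of the 3 PBS libraries (blue) and the 3 CSE libraries (orange). Cyp1a1 lay at a mean of 0.0623 TPM in PBS and 34.5 TPM in CSE, Krt19 at 1010 and 493 TPM, and Zbp1 and Cd36 stayed under 1 TPM in each library.

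Other metabolic lists held few changed genes, and their counts moved when 1 library was left out. In fatty acid oxidation, Hadh (0.55 ± 0.11), Decr1 (0.46 ± 0.09) and Eci1 (0.34 ± 0.09) rose and Cpt1b fell by 0.88 ± 0.20 among 22 tested (camera, adjusted p = 0.102, but called at an adjusted p = 0.0414 without PBS replicate 1, when 7 genes rose; 1 rose without CSE replicate 3), with 93.7% of the words of Cpt1b shared with another gene. Of 8 PPAR targets, Pdk4 rose by 0.90 ± 0.16 and Acot1 by 0.31 ± 0.08 (camera, adjusted p = 0.138), with 3 higher without PBS replicate 1 and 1 lower without PBS replicate 2. In glycolysis and the hypoxia response, the glucose transporter gene Slc2a1 rose by 0.51 ± 0.10, Aldoa reached an edgeR adjusted p of 0.0499 at 0.25 ± 0.07, and Ndrg1 fell by 0.70 ± 0.12 among 18 tested (camera, adjusted p = 0.922), and 2 were lower without PBS replicate 2. Of 20 lysosome and autophagy genes, Map1lc3b, Wipi1, Tfeb and Lamp1 fell, by −0.37 ± 0.07, −0.31 ± 0.06, −0.46 ± 0.10 and −0.33 ± 0.08 (camera, adjusted p = 0.196), but 1 fell without CSE replicate 3 and 2 others rose without PBS replicate 1. The metallothionein genes Mt1 and Mt2 and the zinc exporter gene Slc30a1 were not called by edgeR, DESeq2 or limma-voom, 0 of the 3 had an unadjusted p under 0.05, and the list's median (−0.01) and mean (−0.03) differed in sign from camera's direction (adjusted p = 0.975).

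Interferon and cell cycle genes were largely not called. None of 23 tested interferon-stimulated genes was called by edgeR, DESeq2 or limma-voom, although 2 were higher and 2 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.289). None of 22 genes of the G2 and M phases was called by these tools, with 1 at an unadjusted p under 0.05 (camera, adjusted p = 0.341). With 1 library left out, edgeR called 1 interferon-stimulated gene higher (without PBS replicate 2) and 1 lower (without PBS replicate 1), and 1 G2 and M phase gene lower (without PBS replicate 1). Among 22 S phase genes, Ccne1, which encodes cyclin E1, rose by 0.48 ± 0.09 (camera, adjusted p = 0.289). In the senescence list of 16 tested genes, those that changed included the growth factor genes Ereg (1.57 ± 0.14) and Areg (1.54 ± 0.14) and Cdkn1a, which rose, and Igfbp5, which fell by 0.90 ± 0.08 (camera, adjusted p = 0.245), and 4 were lower without PBS replicate 2.

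Leukocyte, endothelial and airway markers were low. Of 16 leukocyte markers, 2 had enough counts to be tested, Csf1r (0.94 ± 0.21, with 1.76 TPM in PBS and 2.00 TPM in CSE) and Cd68, which was not called, while Ptprc stood at 0.137 TPM in PBS and 0.230 TPM in CSE. Csf1r passed the test, a call lost with an offset for effective length and with limma on TPM. Among 5 tested endothelial markers, Tek fell and the list was not called (camera, adjusted p = 0.142). The endothelial gene Cdh5 had 0 counts in the 6 libraries. Of 3 tested airway markers, Muc5b fell by 1.25 ± 0.19 from 1.12 TPM (camera, adjusted p = 0.289). In the mesenchymal list, Col1a1, Dcn and Sparc fell, by −0.60 ± 0.07, −0.83 ± 0.10 and −0.44 ± 0.08, and Pdgfra rose by 0.84 ± 0.12, among 13 tested, without a call of the list (camera, adjusted p = 0.321). Dcn went from 954 to 507 TPM.

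Of the 30 lists with at least 3 tested members, camera with a preset correlation called 11, 7 higher and 4 lower. Only the calls of the cholesterol synthesis list and the AhR list held with an estimated correlation. A call lost in that setting does not by itself point to correlated genes. The estimated correlation was 0.014 for epithelial structure genes, near the preset 0.01, yet camera's unadjusted p went from 3.38e-06 to 0.0104. For NF-kB genes it was −0.022, and camera's unadjusted p went from 0.0033 to 0.0345. Among the lists that lost their call it was highest for ribosomal protein genes, at 0.785. The rotation test fry, which asks whether the genes of a list move on balance in one direction without comparing them with other genes, called 17 lists, among them necroptosis (adjusted p = 0.0053) and heat shock (adjusted p = 0.0136), but not ribosomal protein or oxidative phosphorylation genes (adjusted p = 0.23 for each). The mixed form of fry, which allows changes in both directions, passed for most lists, including lipolysis (fry mixed adjusted p = 0.000221) and glycolysis (3.72e-05). It did not pass for ribosomal protein (0.161), oxidative phosphorylation (0.22), mitochondrially encoded (0.462), G2 and M phase (0.358), chaperone (0.329) or metallothionein genes (0.773).

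Of 167 called genes that were in a list or named by the rule, 49 lost their call when at least 1 library was left out. Among the genes named above, these were Trib3, Mthfd2, Psat1, Sesn2, Chac1, Ocln, Esrp1, Krt8, Sesn1, Ccng1, Lipe, Ces1d, Sftpc, Lpcat1, Slc27a1, Cpt1b, Decr1, Eci1, Acot1, Aldoa, Wipi1, Tfeb, Lamp1, Hspe1, Hspa4l, Atf3, Lcn2, Saa3, Csf1r, Rpl5 and Ndufb3. Their highest adjusted p in edgeR's test lay between 0.0507 (Lcn2, without CSE replicate 3) and 0.196 (Ndufb3, without CSE replicate 3).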

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

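The GC and length correction was chosen after the results were seen; the other alternatives were planned. Across scaling by RLE (1545 genes), library size (1535), DESeq2 (1582), limma-voom (1564), a minimum mean of 5 CPM (1474), no filter on low counts (2197), an effective length offset (1203) and the GC and length correction (1783), the number of changed genes stayed within 1.5 times the 1539 reported, although higher genes numbered 1052 with no filter and 920 after the correction. limma called 998 genes (224 higher) on log2(TPM + 1) and 985 (220 higher) on log2(TPM + 0.1), and a test against a 1.5-fold change called 161 (68 higher, 93 lower), which follows from its stricter hypothesis; the cause of the others was not tested. Leaving out 1 library gave 837 to 1941 changed genes, 281 to 967 higher and 554 to 981 lower. Of 81 called genes named by the rule, of which 69 had a value under the stricter filter and 79 on TPM, between 67 and 81 kept their call under each alternative other than the 1.5-fold test, which kept 35, and none changed sign. Camera called 11 lists with RLE, library size or the stricter filter, 10 or 11 with 1 library left out and 10 after the correction. Without PBS replicate 1 the p53 list lost its call (adjusted p = 0.0707) and fatty acid oxidation gained one (0.0414), and p53 also lost it without PBS replicate 2 (0.08) or CSE replicate 2 (0.0595). With an estimated correlation it called 2 (1 higher, 1 lower), and fry called 17 (9 higher, 8 lower). The direction of the test turned for 4 lists, none of them called in either setting. Their median log2 changes where it turned, and their range with each library left out, were as follows: endoplasmic reticulum chaperones −0.072 to 0.018 (0.016 without PBS replicate 1), glycolysis 0.023 under fry and −0.02 to 0.065 with 1 library left out, lipolysis 0.114 under fry, −0.069 with the stricter filter, 0.082 after the correction and 0.022 to 0.155, and metallothioneins −0.012 under fry, −0.025 with library size scaling, −0.022 with the stricter filter, −0.074 after the correction and −0.137 to 0.11. A list's median need not turn when the direction of its test does. Ripk3 turned with the effective length offset (−0.079), on log2(TPM + 1) (−0.105) and on log2(TPM + 0.1) (−0.138), on 94 counts in total; the cause was not tested.

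The replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at −0.124, 0.006 and −0.059. With the number as a block, 1022 genes changed (331 higher, 691 lower), 1010 of them among the 1539, and the same 11 lists were called. Depth limits genes such as Zbp1 and Cd36, with 30 and 22 counts in total over the 6 libraries.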

Other observations

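The gene families in the next 2 paragraphs, the LXR, YAP and mesothelial lists and the tests of the ribosomal and oxidative phosphorylation genes by list, the tests of gene sets by other splits of the libraries, and every test after removal of the GC and length trend, were chosen after the results were seen. Beyond the lists of the report, 11 further lists were tested, and the enzyme families among them moved to different extents. Of 18 tested glutathione S-transferase genes, 7 rose in edgeR's test, among them the microsomal Mgst1, from 528 to 906 TPM, and the rest were not called (median 0.31, camera adjusted p over the 11 lists = 2.14e-07, and adjusted p = 0.159 with an estimated correlation). Of 15 heme metabolism genes 4 rose: Cpox, an enzyme of heme synthesis, by 1.71 ± 0.09 from 134 to 381 TPM, the biliverdin reductase Blvrb by 1.20 ± 0.09, the porphyrin transporter Abcb6 by 0.49 ± 0.08 and Alas1 by 0.37 ± 0.08, a call lost without PBS replicate 3 (edgeR adjusted p = 0.0551) (camera adjusted p = 0.000565, and adjusted p = 0.159 with an estimated correlation). Of 14 retinoid metabolism genes, Rdh10 rose by 2.01 ± 0.09, Adh7 by 1.94 ± 0.07, Dhrs3 by 1.30 ± 0.11, Bco1 by 1.32 ± 0.29 (lost without PBS replicate 3, edgeR adjusted p = 0.0542, or CSE replicate 1) and Cyp26b1 by 0.52 ± 0.09, while the retinal dehydrogenases Aldh1a2 and Aldh1a3 fell by 1.37 ± 0.10 and 1.29 ± 0.15 (camera adjusted p = 0.0134, and adjusted p = 0.164 with an estimated correlation). Of 5 UDP-glucuronosyltransferase genes, Ugt1a6a, Ugt1a6b and Ugt1a7c rose, which share most of their sequence (camera adjusted p = 0.000651, and adjusted p = 0.149 with an estimated correlation). Aldehyde dehydrogenases were not called as a list (camera adjusted p = 0.193): of 19, Aldh3a1, Aldh1l2, Aldh7a1 and Aldh2 rose, the last not without CSE replicate 2 (edgeR adjusted p = 0.0848) or any of 3 other libraries, and Aldh1a2 and Aldh1a3 fell. Of 9 aldo-keto reductases 0 rose in edgeR's test and Akr1b3 fell, a call lost without CSE replicate 2 (edgeR adjusted p = 0.106) or either other CSE library (camera adjusted p = 0.962).

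Mesothelial markers were lower as a group. Of 10 tested, 8 fell, including Upk3b (fell by 1.63 ± 0.08, from 88.8 to 27.1 TPM), Lrrn4 (fell by 1.24 ± 0.24) and Msln, while Wt1 stood at 0.03 ± 0.15 (median −1.30, camera adjusted p = 9.27e-10, and adjusted p = 0.0271 with an estimated correlation). Growth factor genes went both ways. Of 9 tested EGF family ligands, Ereg, Areg and Btc rose and Egf and Nrg1 fell, by −1.09 ± 0.12 and −0.41 ± 0.08 for the last pair, and the list was not called (camera adjusted p = 0.962, with a median of −0.24 against a mean of 0.10). Fgf18 fell by 1.23 ± 0.10, from 73.3 to 29.4 TPM, and Fgf16 fell from 7.91 to 2.82 TPM, out of 8 FGF genes tested (camera adjusted p = 0.0273, and adjusted p = 0.159 with an estimated correlation).

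The real grouping gave 1539 changed genes and the highest of the other 9 splits of the 6 libraries gave 1. It gave 11 lists, and the highest other split gave 8. In both cases 1 of the 10 splits, the real one, gave a count as large, and 10 splits are too few for a share under 0.05. Each other split also has libraries of both treatments on each side. An effect of treatment then adds to the spread, so few gene calls are to be expected there, and their number does not measure chance.

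The 23 cholesterol synthesis genes fell together, by a mean of −0.60 (SD over genes 0.21). A GC or length trend between libraries is argued against as the whole cause, since the mean was −0.57 (SD 0.22) after its removal. Camera's adjusted p was then 3.85e-20 with the preset correlation. How much passing the threshold adds to the mean cannot be told from the other splits. Before the removal, all 9 other splits of the libraries gave these genes a camera p under the threshold. The smallest was 1.85e-05, against 1.74e-19 for the real split. Part of any effect of treatment enters these splits, so they do not show how often the threshold is passed without one. Sparser CSE cultures with active YAP, the regulator that density restrains, would raise YAP and TEAD targets. These were lower in CSE (camera p = 0.0027, and p = 0.194 with an estimated correlation), 12 of 14 with lower fitted values. Relative to the PBS mean, they averaged −0.007, −0.085 and 0.092 in the PBS libraries and −0.17, −0.21 and −0.202 in the CSE libraries. For these 14 genes the direction argues against that explanation. The p does not, since 3 of the 9 other splits of the libraries gave them a p as small. Of 14 genes, 3 were called lower, 1 without CSE replicate 2 or CSE replicate 3, and 6 without PBS replicate 2. The YAP list stayed lower with any library left out (camera p between 0.000211 and 0.0237), but the splits limit this p as well. The hypothesis that the cells held more sterol, which may also activate LXR, stays open: LXR targets did not pass (camera p = 0.151, and p = 0.215 with an estimated correlation), with Abca1 higher by 0.54 ± 0.14 as the 1 call among 6, lost without PBS replicate 3 (edgeR adjusted p = 0.0936) or any of 3 other libraries. A direct effect of the extract on the sterol pathway is a further hypothesis. The design cannot tell it apart from an indirect effect, and it was not tested.

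The lower alveolar type 1 and epithelial genes, 26 in all, averaged −0.51 (SD 0.36). Their mean was −0.45 (SD 0.38) after the GC and length trend was removed (camera p = 8.56e-12 with the preset correlation). The mean argues against that trend as the whole cause, although neither list passed with an estimated correlation before its removal (camera adjusted p = 0.102 for each). What passing the threshold adds cannot be told here either. Before the removal, 7 of the 9 other splits of the libraries gave these genes a camera p under the threshold. The smallest was 6.99e-05, against 2.11e-12 for the real split. These splits too hold part of any effect of treatment. A shift in the makeup of the culture, with fewer cells of a subpopulation that carries mesothelial genes, could lower Krt19, Msln and Upk3b together. Of the 9 tested mesothelial markers apart from Krt19, which is in both lists, 88.9% had a 95% interval below 0, with Wt1 as the exception. They did not fall alike, from −2.06 ± 0.17 for Pkhd1l1 to 0.03 ± 0.15 for Wt1, and a loss of such cells cannot be told apart from lower expression within cells without single-cell data.

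Ribosomal protein and oxidative phosphorylation genes were higher by a mean of 0.261 (SD 0.188) in calls made with the preset correlation, which neither list kept with an estimated one (camera adjusted p = 0.542 for each). Whether 1 library makes the rise stays open, although the joint camera p was at most 0.000641 with any of the 6 left out. A p as small also came from splits that mix the treatments, though part of any effect of treatment enters those splits. Without CSE replicate 3 the joint mean shrank to 0.165, the ribosomal mean from 0.316 to 0.205 and the oxidative phosphorylation mean from 0.21 to 0.129. With the preset correlation, the ribosomal list stayed past the threshold after the GC and length trend was removed (mean 0.316, SD 0.213, before and 0.241, SD 0.211, after, camera adjusted p = 0.00266), while oxidative phosphorylation did not (mean 0.21, SD 0.147, before and 0.134, SD 0.137, after, camera adjusted p = 0.0612). The oxidative phosphorylation mean shrank and its spread over genes did not grow. The same limit of the p leaves the trend open for both. Spread between libraries that ignores the treatment may contribute: of the 9 other splits, 2 gave the joint list a camera p as small as the real split's 1.25e-06. The smallest was 8.89e-27, for PBS replicate 1 with CSE replicates 2 and 3 against the rest. A p under 0.05, the bound first used, came from 7 of the 9. That bound cannot tell such spread from an effect of treatment, since all 9 gave the cholesterol synthesis genes a camera p under it. An effect of the extract stays open beside such spread.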
